A study of Mus musculus with 6 samples.

How the data were processed

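Total RNA from B cell precursors that had been transformed with the BCR-ABL1 oncogene was measured on Affymetrix arrays. The labels gave 6 samples, 3 from Dusp6 wild-type and 3 from Dusp6 knockout mice, all on a mixed C57Bl/6-SV129j background. Genotype and replicate number were taken from the sample labels.

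The deposited values are signals on a log2 scale, 1 value per probe set and array. Per the submitters' processing notes, RMA and Partek 6.5 were used. RMA is a method that corrects background, equalises the distributions of the arrays and summarises the probes of a probe set. The version of RMA, the background setting and the level of summarisation are not given in the sources used here. The log2 scale was read from the values, which ran from 3.23 to 14.8 with array medians between 8.38 and 8.42. No further normalization was applied before the tests. For arrays there is no read depth, and their number limits the precision: the median standard error of a log2 difference was 0.051.

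Of the 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 were unnamed here. The Entrez identifiers of 21698 of the named probe sets were found in the reference gene table of GRCm38.p6, and 0 symbols needed an update. That table was used only for names, gene types and the order of genes along chromosomes. Genes with more than 1 probe set (999) were represented by the probe set with the highest mean signal, which left 19938 genes. Every column of the table matched a labelled sample.

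Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, all 6 arrays). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All log2 differences are knockout minus wild type. Errors of group means are standard deviations over 3 arrays, and errors of differences are limma's standard errors.

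Before the data were examined, 30 gene lists were fixed, with 850 of 926 entries measured, where a gene in several lists counts in each. They covered ERK pathway feedback regulators, ERK-responsive transcripts, immediate early genes, other dual-specificity phosphatases (with the tyrosine phosphatase genes Ptpn5, Ptpn6, Ptpn7, Ptpn22 and Ptprr), RAS and MAPK cascade components, STAT5 target genes, FOXO target genes and the PI3K pathway, NF-kB target genes, p53 target genes, cell cycle inhibitors and senescence genes, and the BCL2 family. They also covered B lineage transcription factors, pro-B and pre-B cell genes, pre-BCR and BCR signalling, mature B cell genes, MHC class II presentation, cell cycle and E2F targets, MYC targets and ribosome biogenesis, the type I interferon response, the unfolded protein and heat shock response, NRF2 and the oxidative stress response, glycolysis, cholesterol biosynthesis, and chemokines, adhesion and homing. Lists of myeloid and mast cell, T and NK cell, erythroid and megakaryocyte, and stromal and fibroblast markers, of sex-linked transcripts and of genes flanking Dusp6 completed the set. Lists were tested with limma's camera, which compares the genes of a list with all other genes, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and limma's fry served as alternatives. Medians of lists were also placed among 10000 random lists matched on mean signal.

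Named genes followed a rule fixed at the same time. It took Dusp6, the 12 largest positive and 12 largest negative differences among called genes whose groups did not overlap (leaving out symbols made of Gm and a number, those ending in Rik and those starting with LOC), and up to 4 called members of each list with the largest differences, or the 2 with the smallest p where none passed. Other genes named in the text, such as members that moved against the direction of a list, histone genes, small nucleolar RNAs and neighbours of Zfp979, were chosen after their values were seen.

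The procedures were tested on simulated data drawn from the means and spreads of the 19938 genes of the knockout against wild-type comparison, in 20 runs with 200 changed genes each. The limma test recovered 66.9% of genes changed by 0.25 on the log2 scale, 99.6% at 0.5 and 100% at 1, with 0 calls of the wrong sign. Unchanged genes made up 6.28% of the calls. The data gave 3954 calls, with differences down to 0.13. So many changed genes and changes below 0.25 were not simulated, so these rates need not hold for the data. Camera called a list shifted by 0.15 in 20 of 20 runs and made 1 other call over all runs, with genes simulated as independent. A count of neighbouring pairs of changed genes, run over 19845 genes, passed its bound in 18 of 20 runs with 20 added pairs and in 1 of 20 with random placement.

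Alternatives fixed before the data were examined were a repeated quantile normalization, centring each array on its median, removal of dim genes (below the median, or below the 25th percentile, of mean signal), the mean of a gene's probe sets, a test of every probe set, eBayes with trend and robust options, array weights, the replicate number as a block, and leaving out each array in turn. Principal components and the array correlations were computed to look for samples that stood apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.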

Results

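Gene expression was measured in mouse B cell precursors transformed with BCR-ABL1, the fusion kinase of Philadelphia chromosome-positive acute lymphoblastic leukaemia. Cells from Dusp6 wild-type mice (3 arrays) were compared with cells from Dusp6 knockout mice (3 arrays). Dusp6 is a cytoplasmic phosphatase that removes activating phosphates from ERK. The comparison asks which transcripts differ in transformed cells that lack it. The labels do not say that the arrays of a genotype came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Arrays of one genotype correlated at 0.996 to 0.998 over all probe sets, and arrays of different genotypes at 0.987 to 0.989. The first principal component held 82.2% of the variance and separated the genotypes, and the next held 6.51%.

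Dusp6 itself was 10.3-fold lower in the knockout arrays, with a log2 signal of 12.44 ± 0.072 in wild type and 9.08 ± 0.058 in knockout (SD, n = 3 each; limma adjusted p = 4.3e-10). Its signal fell from the 93rd to 94th percentile of genes on the wild-type arrays to the 55th to 57th percentile on the knockout arrays. The labels do not say which part of the gene was deleted, so whether the probes lie inside it is not known here.

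Many genes differed between the genotypes, most of them by little. Of 19938 genes, 1926 rose and 2028 fell in the knockout cells, which is 9.66% and 10.2% of the genes tested. The median absolute log2 difference of these genes was 0.27, or 1.21-fold. Differences of at least 2-fold were seen in 258 genes, 157 higher and 101 lower. The 3 wild-type and 3 knockout values did not overlap in 7119 genes (35.7%, against 10% by chance), including all 258 genes past 2-fold. Among the 13767 probe sets without a single gene symbol, 1105 passed the same threshold and 187 of those passed 2-fold.

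The genes that rose most were AI506816 (log2 difference 5.25 ± 0.11, SE) and Rgs18, a regulator of G protein signalling (32.0-fold). Ly86, which encodes the partner protein of the B cell surface receptor Cd180, rose 19.8-fold, and Nt5e, an ecto-enzyme that makes adenosine, rose 13.6-fold. Lrrtm2, a synaptic adhesion protein, rose by 3.36 on the log2 scale, the small heat shock protein gene Hspb8 by 3.30, and the aldo-keto reductase gene Akr1e1 by 3.26. The caveolin gene Cav2 (3.15), Lipo3 (3.08), Bin2 (3.05), Mpzl2 (2.87) and the zinc finger gene Zfp263 (2.84) completed the 12 largest increases. The wild-type signals of Akr1e1 (6.26), Cav2 (6.63) and Bin2 (7.05) lay below the lower quartile of the arrays (7.12 to 7.16) and were not tested against background, so the sizes of these differences are less certain. The adjusted p of these genes ranged up to 1.8e-07 (limma, for Lipo3).

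Zfp979, a zinc finger gene, had the largest decrease (log2 difference −6.20 ± 0.11, SE), and its knockout signal of 4.69 lay near the bottom of the array range. Genes near it on the chromosome, Fv1 (−1.10), Zfp600 (−1.81), Zfp980 (−1.44) and Zfp985 (−1.82), also fell past 2-fold. They were picked for passing 2-fold, and nearby genes that did not pass it are not named. Smo, the signal transducer of the Hedgehog pathway, was 12.2-fold lower. Eya1, a transcriptional coactivator, and Trib2, a pseudokinase, were 11.7-fold and 11.6-fold lower. The calpain protease gene Capn2 fell by 3.45 on the log2 scale, the endocytic recycling gene Ehd3 fell by 3.24, and the lysophospholipid acyltransferase gene Lpcat2 fell by 3.02. Tcf7l2, a transcription factor of the Wnt pathway, fell by 2.95, and Dnase1l3 (−2.90), Zc3h12c (−2.82) and Zdhhc15 (−2.69) followed.

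**Figure D1:**
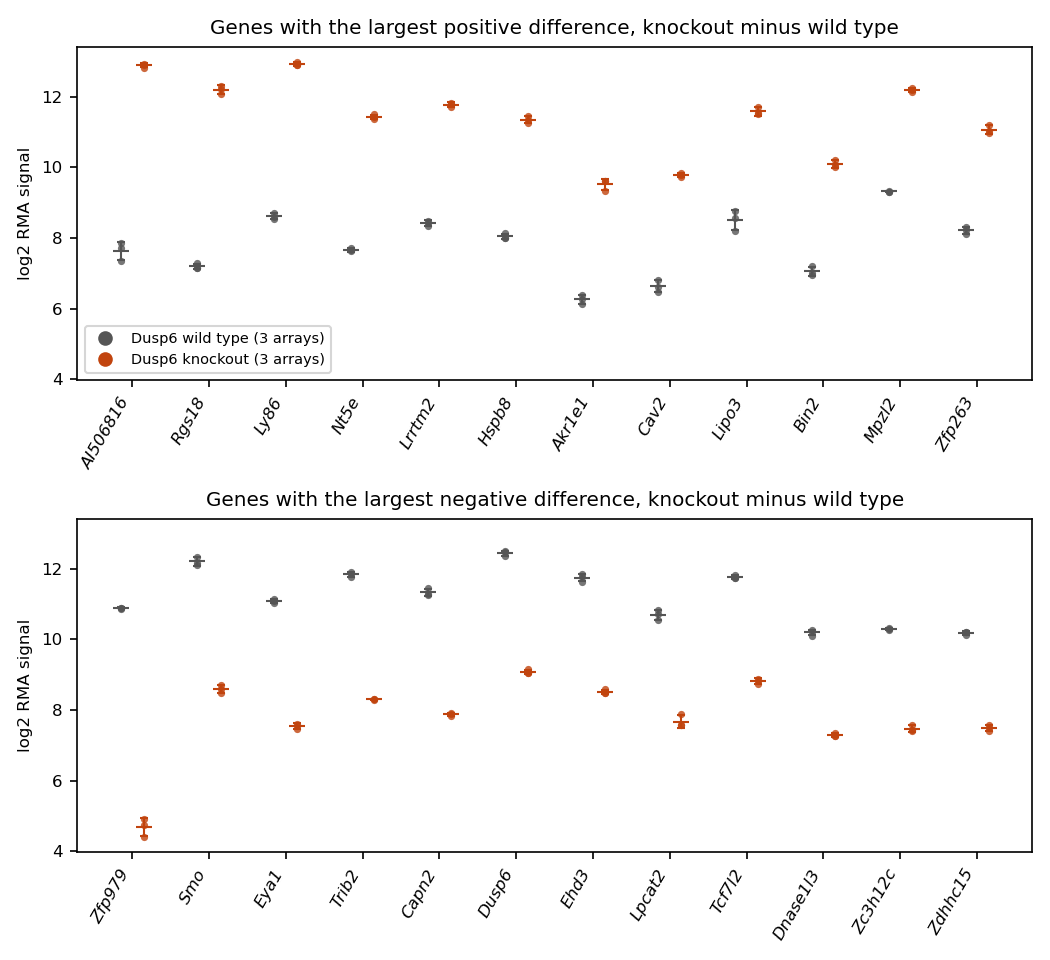
Log2 RMA signal (y axis) of the 12 genes with the largest positive and the 12 with the largest negative difference that met the naming rule, on 3 Dusp6 wild-type (grey) and 3 Dusp6 knockout arrays (orange). Points are single arrays, and the bars mark the group mean and its SD. The groups do not overlap in any of these genes, and Zfp979 shows the widest separation, with a log2 difference of −6.20.

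Genes of the pathway that Dusp6 acts on went both ways. Of 18 ERK pathway feedback regulators, 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.87). Spry4, an inhibitor of receptor tyrosine kinase signalling, fell by 0.39 and the ERK phosphatase gene Dusp5 fell by 0.33. The ERK phosphatase gene Dusp7 rose by 0.37 and the RAS GTPase-activating gene Rasa2 rose by 0.33. Among 28 ERK-responsive transcripts, 6 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.63, but lower by fry with adjusted p = 0.00084). Kcnn4, a potassium channel gene, and Epha2, an ephrin receptor gene, each fell by 1.10, Emp1 fell by 0.99, and the cytokine gene Lif rose by 0.53. The list's median was above 0 (0.010) while its mean and its test pointed down.

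Immediate early genes (34 measured) gave 4 that rose and 8 that fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.30). The antiproliferative gene Btg2 rose by 0.96, whereas Egr1 fell by 0.51, Fosb by 0.39 and Klf10 by 0.37. Other dual-specificity phosphatases gave 4 that rose and 7 that fell of 24 (6 and 8 adjusted over the list alone; camera adjusted p = 0.46), with Dusp10 at −0.48. That list also holds tyrosine phosphatase genes that are not of the dual-specificity class, among them Ptpn22 (−0.60). Of 39 RAS and MAPK cascade components, 4 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.74). Flt3 rose by 0.62 and the kinase gene Map3k8 by 0.53, while the transcription factor gene Elk1 fell by 0.57 and the JNK gene Mapk8 by 0.53. This list's median (0.011) also lay above 0 against a mean and a test below 0.

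Cell cycle genes were lower in the knockout cells. Of 50 measured members, 25 fell and 0 rose (30 and 0 adjusted over the list alone), and 44 had a difference below 0. The shift was small, with a median log2 difference of −0.14, and camera called it (adjusted p = 1.5e-09; adjusted p = 0.032 with an estimated correlation). The mitotic kinase gene Ttk fell by 0.41, the replication genes Gins1 and Cdt1 by 0.40 each, and the transcription factor gene E2f1 by 0.36. Among 25 cell cycle inhibitors and senescence genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.87, direction down, with a mean above 0 and a median below). Cdkn2a, which encodes the tumour suppressors p16 and p19Arf, rose by 1.42 and its neighbour Cdkn2b by 0.49, while Cdkn2c fell by 0.25 and Bcl6 by 0.23.

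Genes of the type I interferon response were higher in the knockout cells. Of 39 members, 24 rose and 3 fell (26 and 3 adjusted over the list alone), with a median log2 difference of 0.24 (camera adjusted p = 2.3e-08; adjusted p = 0.032 with an estimated correlation). The exonuclease gene Isg20 rose by 1.06, the nucleotide kinase gene Cmpk2 by 0.99, Lgals3bp by 0.89 and the RNA helicase gene Dhx58 by 0.76. Herc6, Ifit2 and Mx2, which are also interferon-induced, fell by 0.37, 0.28 and 0.23. Of 29 NF-kB target genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.16, but adjusted p = 0.013 among genes at or above the median signal). With an estimated correlation the camera adjusted p of the NF-kB list was 0.58, whereas fry called it higher (adjusted p = 0.0019). The cytokine genes Lta, Ltb and Tnf rose by 1.49, 0.89 and 0.48, and the stress gene Gadd45b fell by 0.51.

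Several lists of B cell genes shifted upward. In pre-BCR and BCR signalling, 14 of 35 members rose and 3 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0023, but adjusted p = 0.40 with an estimated correlation). The members that rose most were Cd22 (1.33), Cd72 (1.26) and Fcgr2b (1.07), all known as inhibitory receptors of B cells, and the adaptor genes Lcp2 (−0.76) and Blnk (−0.23) were lower. In MHC class II presentation, 8 of 14 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0027, but adjusted p = 0.24 with an estimated correlation). The invariant chain gene Cd74 rose by 2.48, H2-Oa by 0.75 and H2-DMa by 0.50, while the class II chain gene H2-Ab1 fell by 0.81. Among mature B cell genes, 11 of 30 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.038, but adjusted p = 0.54 with an estimated correlation). Cxcr5, the receptor that guides B cells to follicles, rose by 1.45, the DNA sensor gene Tlr9 by 1.44, Ccr7 by 0.94 and Ltb by 0.89.

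The 30 pro-B and pre-B cell genes moved both ways (9 rose and 6 fell, 10 and 7 adjusted over the list alone; camera adjusted p = 0.57). Fry called this list higher (adjusted p = 0.00028). Dntt, the polymerase that adds nucleotides at immunoglobulin junctions, fell by 1.42 and the recombinase gene Rag2 by 0.43, whereas Nt5e rose by 3.76. B lineage transcription factors gave 5 that rose and 5 that fell of 35 (5 and 9 adjusted over the list alone; camera adjusted p = 0.28). Spib and Id2 fell by 0.38 and 0.33, and Bach2 and Pou2f2 rose by 0.30 and 0.29. In chemokines, adhesion and homing, 9 of 28 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.073, but adjusted p = 0.012 among genes at or above the median signal). Those that rose included the integrin genes Itgal (1.10) and Itgb2 (0.78). With an estimated correlation the camera adjusted p of this list was 0.40, whereas fry called it higher (adjusted p = 0.00055).

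STAT5 target genes were called as higher, with 9 of 25 rising and 2 falling (9 and 3 adjusted over the list alone; camera adjusted p = 0.019, but adjusted p = 0.58 with an estimated correlation). Their median of 0.039 lay inside the central 95% of matched random lists (−0.055 to 0.047), unlike those of the other 5 called lists. With any 1 array left out the STAT5 median was 0.050 to 0.063, for which no random lists were drawn. Il2ra, a chain of the interleukin receptor, rose by 2.52, the feedback inhibitor gene Socs3 by 0.75, the survival gene Bcl2 by 0.60 and the kinase gene Pim2 by 0.51. In the BCL2 family, 4 of 15 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.46). Fry called this family higher (adjusted p = 0.037). Its largest change was the rise of the survival gene Bcl2 (0.60), named above. The pro-apoptotic genes Bmf (0.39) and Pmaip1 (0.33) also rose, and the survival gene Bcl2l1 fell by 0.23. Of 34 p53 target genes, 12 rose and 4 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.084, but adjusted p = 0.038 with trend and robust options), with Eda2r at 1.25, Ephx1 at 1.09 and Plk3 at −0.87. With an estimated correlation the camera adjusted p of the p53 list was 0.54, whereas fry called it higher (adjusted p = 0.0018). FOXO target and PI3K pathway genes gave 4 that rose and 6 that fell of 33 (4 and 7 adjusted over the list alone; camera adjusted p = 0.63), with Igf1r at −0.72, S1pr1 at −0.59 and Txnip at 0.36.

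None of the metabolic and stress lists passed in the main test. In cholesterol biosynthesis, 6 of 20 genes fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.056, but adjusted p = 0.032 with trend and robust options), including Nsdhl (−0.56), Stard4 (−0.30), Dhcr7 (−0.27) and Sqle (−0.24). Dhcr7 lost its call without wild-type replicate 3 (adjusted p = 0.051). In NRF2 and oxidative stress response, 2 of 28 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.21), with Gstm1 at −0.57, Gsr at −0.45, Slc7a11 at −0.36 and Blvrb at −0.31. Glycolysis genes gave 5 that rose and 3 that fell of 23 (5 and 3 adjusted over the list alone; camera adjusted p = 0.74), with Aldoc at 0.59, Pdk1 at 0.41, Pfkfb4 at 0.36 and Pfkm at −0.33. In the unfolded protein and heat shock response, 6 of 29 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.46). Chac1, a glutathione-degrading enzyme, fell by 1.15 and Asns by 0.29, and Xbp1 and Pdia4 rose by 0.46 and 0.36. Of 45 MYC target and ribosome biogenesis genes, 2 rose and 3 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.63), with Rrs1 at −0.65, Odc1 at −0.30 and Rrp9 at 0.26.

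Markers of other cell types were not called as groups by camera. Fry tests a list without comparing it with other genes. It called the myeloid and mast cell markers (adjusted p = 0.0019), T and NK cell markers (0.033) and genes flanking Dusp6 (0.044) higher. Of 35 myeloid and mast cell markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.46): Ly86 (4.31), Fcgr3 (1.72) and Lyz2 (0.70) led those that rose, and Csf2ra fell by 0.59. T and NK cell markers gave 4 that rose and 2 that fell of 25 (4 and 2 adjusted over the list alone; camera adjusted p = 0.28), with Cd2 at 1.02, Klrd1 at 0.61, Lat at −0.44 and Cd5 at 0.26. Of 27 stromal and fibroblast markers, Serpinf1 (0.48) and Fn1 (0.22) rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.28). Fn1 lost its call without wild-type replicate 1 (adjusted p = 0.071), knockout replicate 1 (0.060) or knockout replicate 2 (0.071). Of 17 erythroid and megakaryocyte markers, Car1 rose by 0.16 and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.87, direction up, with a median below 0). Car1 lost its call without any 1 array except knockout replicate 3 (adjusted p from 0.051 to 0.107). Of 8 sex-linked transcripts, 0 passed in limma over all genes or adjusted over the list alone, and 0 at an unadjusted value under 0.05 (camera adjusted p = 0.87). Sry differed by −0.087 (adjusted p = 0.27) and Zfy1 by 0.098 (adjusted p = 0.31). Among 28 genes fixed as flanking Dusp6, 3 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.87, direction up, with a median below 0). Plxnc1 rose by 0.67 and Btg1 by 0.38, and Poc1b fell by 0.22 and Cep290 by 0.20. Cep290 (adjusted p = 0.0496) lost its call without any 1 array except wild-type replicate 3 (adjusted p from 0.064 to 0.161).

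**Figure D2:**
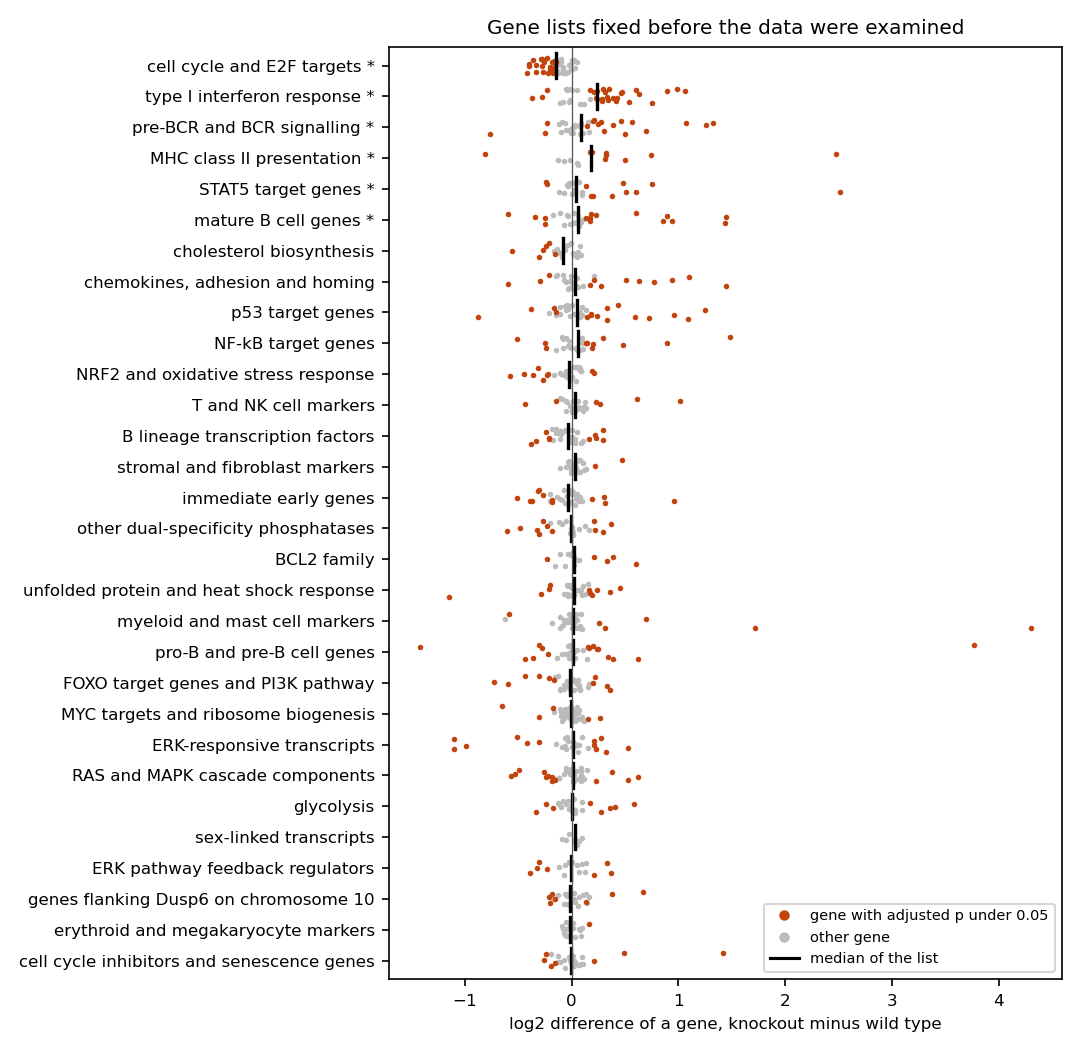
Log2 difference of each measured member (x axis, knockout minus wild type) of the 30 gene lists (y axis, in order of the camera p). Orange points are genes with a limma adjusted p under 0.05, grey points are other genes, black bars are list medians, and asterisks mark the 6 lists with a camera adjusted p under 0.05. The cell cycle median lies at −0.14 and the interferon median at 0.24.

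With an estimated correlation, 2 of the 6 called lists kept a camera adjusted p under 0.05, those of the cell cycle and the interferon response. Their estimates (0.0062 and −0.0067) lay below the preset 0.01, yet their adjusted p was larger than with the preset. A lost call in this setting is therefore not by itself a sign of correlated members. Estimates were 0.012 for MHC class II presentation, 0.046 for mature B cell genes, 0.056 for pre-BCR and BCR signalling and 0.12 for STAT5 target genes. The mature B cell list was also lost without wild-type replicate 2 (adjusted p = 0.052) and without knockout replicate 1 (adjusted p = 0.063).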

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

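The alternatives in this part were chosen before the data were examined. Over the settings run, the genes called higher numbered 1491 to 2189 and those called lower 1512 to 2435, each within 1.5 times the values reported, and Dusp6 stayed between −3.40 and −3.33 at an adjusted p under 0.05. Genes past 2-fold numbered 244 to 267 except for genes at or above the median signal, which left 188 of fewer genes tested, and for a test of every probe set, which adds unnamed probe sets and gave 466. Centring each array on its median gave 1683 higher and 2435 lower (40.9% higher). With the replicate block the counts were 1681 higher, 1764 lower and 258 past 2-fold, but arrays with the same number did not deviate together (correlations 0.0098, −0.12 and 0.053), so the numbers were not taken to pair the samples. Lists called higher numbered 5 as reported, 1 with an estimated correlation, 14 by fry, which tests a list without comparing it with other genes, and 4 to 7 in the other settings. Camera gained 2 with genes at or above the median signal, NF-kB target genes (adjusted p = 0.013) and chemokines, adhesion and homing (0.012). With trend and robust options it gained p53 target genes (0.038) and chemokines, adhesion and homing (0.037). Lists called lower numbered 1 as reported, 2 with trend and robust options, 2 with the replicate block, 3 by fry (cell cycle, ERK-responsive transcripts and NRF2) and 1 to 2 when each array was left out. Cholesterol biosynthesis was the added list with trend and robust options, with the block, without wild-type replicate 1 and without knockout replicate 3, and the cause was not tested. The list of cell cycle inhibitors and senescence genes, not called by camera and with a median of −0.0087, was called higher by fry (adjusted p = 0.027), and the cause was not tested. The mature B cell list was lost in 5 of 16 settings, with adjusted p from 0.016 to 0.063 over left-out arrays, and the cell cycle and interferon lists in 0 of 16. Of 125 named genes besides Dusp6 over 14 settings, 0 reversed and 25 results lost their call, all of Rrp12, Dhcr7, Car1, Fn1 or Cep290. The number of arrays limits what can be called, and signals near the array floor limit the fold of genes such as Zfp979, Akr1e1, Cav2 and Bin2.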

Other observations

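The groups in this paragraph and the next were chosen after their values were seen. Of 8 Gimap genes measured, which encode immune GTPases, 7 rose and 0 fell: Gimap4 by 1.82, Gimap6 by 1.46, Gimap7 by 1.03 and Gimap3 by 0.65, with Gimap9 (0.33), Gimap5 (0.30) and Gimap1 (0.23) rising less and Gimap8 at 0.15 (limma adjusted p = 0.096). They lie next to one another, so they are not independent, and the nearby Tmem176b (1.40), Igf2bp3 (2.50) and Fam221a (1.39) also rose. The counts were the same after a repeated quantile normalization. Tumour necrosis factor receptor genes gave 6 that rose and 1 that fell of 20, led by Tnfrsf19 (1.36) and Tnfrsf21 (0.80).

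Among 237 families of at least 10 genes formed from gene symbols, 5 passed camera with the preset correlation, and 0 with an estimated correlation (adjusted p = 0.997, with 3 families at an unadjusted value under 0.05). They were the Snord (0 rose and 19 fell of 31), Snora (1 and 9 of 20), Rad (0 and 10 of 17), Mcm (0 and 7 of 10) and Tnfrsf families. Mcm2, Mcm3, Mcm4, Mcm5 and Mcm6, which fell, also belong to the cell cycle list, so the Mcm family partly repeats that result. The Mir family did not pass (12 rose and 10 fell of 291; camera adjusted p = 0.85). Of the 53 genes typed as small nucleolar RNA in the reference gene table, a set without Snord73b (−0.51), 28 fell and 1 rose. Those that fell included Snord118 (−0.55) and Snora73b (−0.55), and Snora2b rose by 0.42. Of 30 histone genes, 18 fell and 0 rose. Those that fell most were H3c15 (−1.33), H4c3 (−0.82) and H1f1 (−0.67). Camera with an estimated correlation, over 5 groups picked after their values were seen, gave adjusted p = 0.016 for Gimap genes, 0.097 for histones, 0.16 for small nucleolar RNAs, 0.17 for their 5 host genes named Snhg and 0.85 for microRNAs. These values do not support any group independently, because the groups were picked on the same data.

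Of the tests below, those on the region around Dusp6, on single cultures, on myeloid cells, on the signal level, on few cell cycle members and on the direction of pairs were chosen only after the result was seen, as was the count with 1 gene per tandem family. The first pattern is the 258 differences past 2-fold, in cells whose labels give a mixed C57Bl/6-SV129j background, so that chromosome segments of different parental strain could differ between the genotypes. Pairs of such genes within 10 measured genes of each other numbered 47, against a median of 35 and a 95th percentile of 45 over 10000 random placements matched on signal (permutation p = 0.027), and 42 against 31 and 41 with 1 gene per tandem family (permutation p = 0.043). Of the 47 pairs, 34 moved the same way, against a median of 25 and a 95th percentile of 30 with directions permuted (permutation p = 0.0045), with tandem families such as Gimap and the Zfp979 group counted more than once. The excess is small, 1 window size was run, and neighbours that share regulation would give both values too, so strain segments remain a candidate explanation for part of the pattern. Of the 100 measured genes nearest Dusp6, 29% passed the threshold, between the median (20%) and the 95th percentile (30%) of 361 windows elsewhere, which leaves a strain segment around Dusp6 open. A single culture per genotype cannot be told apart from the effect of Dusp6, because the labels name no separate cultures. The lowest correlation between arrays of a genotype, 0.998 over genes, does not decide this. Arrays of different genotypes also correlated highly, at 0.987 to 0.989 over all probe sets.

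The second pattern is the rise of some genes of the myeloid and mast cell list, Ly86 by 4.31, Fcgr3 by 1.72 and Lyz2 by 0.70. Of its 35 members, 5 rose, 1 fell and 29 did not pass. Camera did not call the list (adjusted p = 0.46), whereas fry called it higher (adjusted p = 0.0019). Myeloid cells in the knockout cultures would also bring their abundant transcripts, but 10 of these (Csf1r, Tyrobp, Fcer1g, Itgam, Cd68, Cd14, Mpo, Elane, S100a8 and S100a9) had a median log2 difference of 0.014, between −0.18 and 0.083, with 0.195 as the highest upper 95% bound. The 10 were chosen after the values were seen and hold none of the listed markers that rose, such as Lyz2. They show no called rise of these transcripts, but cannot decide whether myeloid cells were the source. Over the 35 markers fixed beforehand, the median was 0.016, with 20 members above 0 and 15 below. Myeloid cells in the cultures and a change of Ly86, Fcgr3 and Lyz2 within the transformed cells stay open as hypotheses and were not told apart.

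The last pattern is the fall of the cell cycle list and the rise of the interferon list. A trend with signal level between the arrays would give the same shift to random genes of like signal, but the cell cycle median of −0.14 lay below the central 95% of 10000 matched lists (−0.039 to 0.031) and the interferon median of 0.24 lay above theirs (−0.046 to 0.038). A few members alone would leave the median inside that range, so the median of −0.14, with 44 of 50 members below 0, argues against that. Strain segments, a difference in growth state between cultures and an effect of Dusp6 loss remain open and were not tested for these lists.

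With 10 splits of 3 against 3 arrays, the share of splits as large as the real one is never under 0.1, so only the values are given. The real split was the 1 of the 10 that reached its counts: 3954 genes past the threshold against 0 for the highest other split, 258 genes past 2-fold against 0, and 6 lists against 4. Every other split mixes the genotypes, so their difference widens the spread within both groups. Low gene counts there would follow from any large difference between the groups and do not bear on its cause.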
